A study of Mus musculus with 10 samples.

How the data were processed

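ChIP-seq of H3K4me3, H3K4me1, H3K27me3 and H3K9me3 was performed on Glast+ cells of C57BL/6 mouse retinas at postnatal day 28, with 2 experiments per mark. Per the labels' protocols, cells were fixed with formaldehyde, chromatin of 25000 cells was used per immunoprecipitation, and libraries were made from 500 pg of DNA and sequenced as single-end reads of 50 bp. The 10 libraries of the series include 2 input libraries, which were not analysed here. Samples were grouped by mark from their labels, with the experiment number as replicate. Nothing in the labels says which animals each experiment drew on, so the spread between experiments may be partly technical.

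The authors deposited 1 list of islands per ChIP library. Reads were processed with FastQC, BWA 0.7.5a, SAMtools 1.3.1, bedtools 2.17 and SICER on mm10, per the submitters' processing notes. SICER joins enriched windows across gaps into islands. Its settings and the control are not given in the sources used here. Each island in the deposited files has a position and a p-value, and whether that value is a p or a q is not stated. Island starts and widths were whole multiples of 200 bp for H3K4me1 and H3K4me3, 3000 bp for H3K9me3 and 5000 bp for H3K27me3, and the smallest gaps between islands were 800, 800, 24000 and 35000 bp. The marks were therefore called at different resolution, which widens the repressive islands, joins neighbouring ones, and makes overlap with a gene end more likely. Some islands had a p-value above 0.05, from 0 in the H3K4me3 lists to 1081 in H3K4me1 of Exp2. The p-values are the authors'. They were used to filter islands within a list, and those of H3K9me3 islands over the Hox clusters are quoted. The files hold no read counts, so the depth per library is unknown and no interval that needs it was computed.

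Island ends are the last base counted from 0, so widths were end minus start plus 1. Islands were laid on bins of 200 bp. Overlap between experiments, marks and gene regions was compared with 1000 circular shifts within each chromosome, leaving out its first 3 Mb, which are unsequenced in mm10. P-values of the shifts are two-sided permutation p-values with Benjamini-Hochberg adjustment over the pairs or regions compared. The smallest they can give is 0.002.

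Gene positions came from an NCBI RefSeq gene table of GRCm38.p6, which has the coordinates of mm10. Of its 21900 protein-coding genes, 21887 lay on the chromosomes in the lists. The table gives gene start and end without strand or transcripts. The promoter windows planned around transcription starts were therefore replaced by windows of 1 kb either side of both gene ends, so an island of a neighbouring gene can mark an end. A gene counted as marked when an island overlapped the same end by 1 bp or more in both experiments. Each of 24 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 120 tests, and log2 odds ratios were computed with 0.5 added to each cell. The lists covered Müller glia, retinal progenitors, neurogenic genes, rods, cones, bipolar, amacrine, horizontal and ganglion cells, microglia, endothelium, pericytes, astrocytes, pigment epithelium, pluripotency, the cell cycle, inhibitors of cyclin-dependent kinases, transcription factors of other lineages, housekeeping genes, Hox genes, Zfp zinc fingers, olfactory and vomeronasal receptors and clustered protocadherins. All symbols written out in the lists matched a gene. Broad islands were the widest 5% of H3K4me3 islands at gene ends, by the smaller width of the 2 experiments. Distal H3K4me1 regions lay over 2.5 kb from the ends of protein-coding and lncRNA genes and were counted within each gene and up to 10 kb from it. List medians were compared with 10000 random lists matched on gene length. Tests between retinal lists were added after the files were seen.

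Lists, tests and alternatives were fixed before the data were examined, except where the text says otherwise. Genes were named by 3 rules. A fixed set, of which some members are not reported here, was always named: Slc1a3, Glul, Rlbp1, Sox9, Aqp4, Sox2, Pax6, Atoh7, Neurog2, Neurod1, Olig2, Nrl, Crx, Otx2, Opn1sw, Pou4f1, Pou4f2, Tfap2a, Gad1, Onecut1, Pou5f1, Nanog, Lin28a, Cdkn1b, Ccnd1, Gata4, Hoxa13, Aif1, Pecam1 and Rpe65. In each list, up to 4 members of the commonest state and up to 4 of other states were named in list order. The 10 genes with the widest H3K4me3, H3K27me3 and H3K9me3 islands were eligible, of which a few are named. Prph2 and Gpr37 were chosen after their values were seen.

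Alternatives were each experiment alone, a mark in either experiment, windows of 500 bp and 2.5 kb, coverage of at least 50% of the window or island, islands with a p-value at or below the median of their file, marks combined within each experiment as a replicate block, no sex chromosomes, no olfactory and vomeronasal receptor genes in the background, the widest 10% of islands, and distal regions over 5 kb from gene ends within 50 kb of genes. Added after the files were seen were windows over the whole gene, genes with no other gene within 5 kb, overlap without 100 kb around receptor genes, and list means of distal regions. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The tests were also tried on simulated data. Circular shifts called 0 of 20 independent maps and all 20 maps with planted overlap. The independent maps were the H3K9me3 map moved by such a shift, so few calls were to be had by construction. Over 21887 genes, the list test called 1.5% of 200 unchanged lists of 20 genes and 95% of 40 lists planted at 70%. There, marks were drawn for each gene separately and lists at random. The 1.5% therefore does not cover lists of neighbouring genes that share islands. The random-list test called 0% of 60 unchanged lists and 100% of 40 planted ones.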

Results

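Histone H3 modifications were mapped in Glast+ cells from the retinas of C57BL/6 mice at postnatal day 28 by chromatin immunoprecipitation and sequencing (ChIP-seq). Glast, encoded by Slc1a3, is the glutamate transporter by which Müller glia, the radial glia of the retina, are commonly isolated. The series maps chromatin state in these cells. It covers 4 modifications: H3K4me3, found at active promoters, H3K4me1, found at enhancers and around promoters, H3K27me3, deposited by Polycomb complexes, and H3K9me3, a mark of heterochromatin. Each was profiled in 2 experiments, named Exp1 and Exp2, which gives 8 lists of enriched regions, called islands. There is 1 cell population and no treatment, so the comparisons are between marks, between experiments, and between groups of genes within these libraries. Read counts were not used here, so the depth behind each list is unknown. With 2 experiments per mark, an exact two-sided permutation test between marks cannot reach 0.05, so differences between marks are given as values with their spread.

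Islands of the repressive marks covered far more of the genome than those of the H3K4 marks. The repressive islands were called in wider windows and joined over wider gaps, which raises both their width and their coverage. The marks are therefore not compared at equal resolution, and how much of the difference comes from the calling was not tested. H3K27me3 islands covered 23.2% ± 4.71 of the genome (SD, n = 2) and H3K9me3 islands 20.5% ± 3.39. H3K4me1 islands covered 7.42% ± 2.87 and H3K4me3 islands 2.27% ± 0.0882. The median island was 65 kb wide for H3K27me3, 37.5 kb for H3K9me3, 3.1 kb for H3K4me1 and 2.8 kb for H3K4me3 (means of the 2 experiments). Exp1 gave more islands than Exp2 for H3K27me3 (7743 and 4105), H3K9me3 (9690 and 5621) and H3K4me1 (52342 and 37200), and fewer for H3K4me3 (16761 and 20169). The X chromosome was covered by H3K9me3 over 42.4% ± 1.42 of its length, against 19.6% ± 3.45 of the autosomes. H3K4me1 covered 1.20% ± 0.141 of the X chromosome and 8.12% ± 3.17 of the autosomes.

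The experiments were compared to see how far the islands of 1 were found again in the other. Of the H3K4me3 islands, 95.6% of those in Exp1 overlapped an island in Exp2, and 80.6% of those in Exp2 overlapped one in Exp1. For H3K4me1 the shares were 52.2% and 86.8%, for H3K27me3 51.3% and 97.0%, and for H3K9me3 57.9% and 99.3%. The covered length shared by both experiments, divided by the length covered in either, was 0.592 for H3K4me3, 0.433 for H3K4me1, 0.609 for H3K27me3 and 0.672 for H3K9me3. The shared length exceeded the mean of 1000 random circular shifts along each chromosome 29.9-fold for H3K4me3, 7.66-fold for H3K4me1, 3.06-fold for H3K27me3 and 3.49-fold for H3K9me3. Each had a two-sided permutation p of 0.002, the smallest these shifts can give.

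Regions covered in both experiments were then compared between marks, to see which marks share territory and which avoid each other. H3K27me3 and H3K9me3 shared 300.0 Mb, which was 64.3% of the H3K27me3 length and 68.4% of the H3K9me3 length, and 3.41-fold the mean of the shifts (log2 1.77). H3K4me3 and H3K4me1 overlapped 13.1-fold more than the shifts (log2 3.71), with 67.1% of the H3K4me3 length inside H3K4me1. H3K4me1 was depleted from H3K9me3 (log2 -3.42) and from H3K27me3 (log2 -1.22). H3K4me3 was depleted from H3K9me3 (log2 -1.24), and less so from H3K27me3 (log2 -0.47), where 13.1% of its length lay. All 6 pairs had an adjusted two-sided permutation p of 0.002, the smallest possible. The depletion of H3K4me3 depended on Exp1. With Exp2 islands alone, H3K4me3 overlapped H3K27me3 slightly more than the shifts (log2 0.18, permutation p = 0.002), against -0.42 with Exp1 alone, and its depletion from H3K9me3 did not pass (log2 -0.06, permutation p = 0.284), against -0.77 in Exp1. The values of H3K4me1 also lay nearer 0 in Exp2, with log2 -1.11 against H3K9me3 and -0.31 against H3K27me3.

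**Figure D1:**
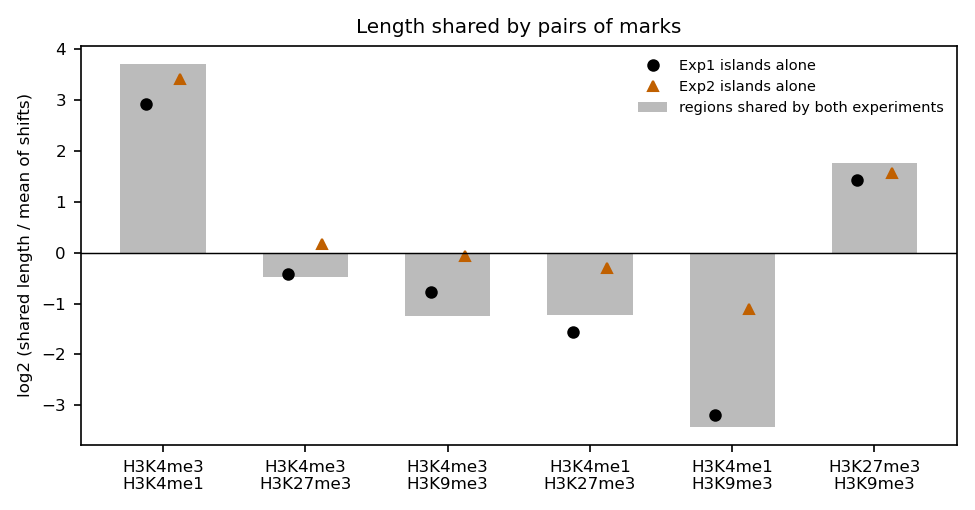
Length shared by each pair of marks over the mean of circular shifts, on a log2 axis. Grey bars stand for regions covered in both experiments, circles for Exp1 islands and triangles for Exp2 islands; H3K27me3 with H3K9me3 lies at 1.77, and H3K4me3 with H3K27me3 lies below 0 in Exp1 (-0.42) and above it in Exp2 (0.18).

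H3K4me3 and H3K4me1 were enriched at gene ends, and most of the length of the repressive marks lay between genes. Windows of 1 kb either side of both annotated ends of protein-coding genes held 37.0% ± 0.134 of the H3K4me3 length (SD, n = 2), 10.5-fold the mean of the shifts, and 42.4% ± 2.57 lay in the rest of genes, 1.09-fold the mean (largest adjusted permutation p = 0.04). The same windows held 13.6% ± 2.31 of the H3K4me1 length, 3.83-fold the mean, and a further 64.1% ± 3.08 of it lay in the rest of genes. Of the H3K27me3 length, 77.6% ± 1.36 lay between genes, and of the H3K9me3 length 83.5% ± 1.02. H3K9me3 was depleted from gene ends (0.686-fold). The largest adjusted permutation p over both experiments was 0.00218 for the other shares. For H3K27me3 at gene ends the experiments differed in direction, with 0.935-fold the mean in Exp1 (adjusted permutation p = 0.0188) and 1.16-fold in Exp2 (adjusted permutation p = 0.00218).

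Genes were classed by the marks at their annotated ends, 1 of which is the transcription start, to describe active, repressed and doubly marked genes. A gene counted as marked when the same end was marked in both experiments. Of 21887 protein-coding genes, 11362 (51.9%) carried H3K4me3 without H3K27me3 and 3640 (16.6%) H3K27me3 without H3K4me3. Both marks lay at the same end of 1256 genes (5.74%), the combination called bivalent, and at different ends of 205 genes. The islands come from many cells, so both marks at an end need not lie in the same cells. Neither mark was found at 5424 genes (24.8%). H3K4me1 lay at 11940 genes, including 83.3% of those with H3K4me3. H3K9me3 lay at 2931 genes, of which 83.7% also carried H3K27me3, while 3.55% of H3K4me3 genes carried H3K9me3. H3K4me3 and H3K27me3 coincided less often than independent marks would, with an odds ratio of 0.192 over genes (Fisher's exact test, p too small to be told from 0). The odds ratio was 31.7 for H3K27me3 with H3K9me3. The share with both H3K4me3 and H3K27me3 at the same end fell to 0.95% when only islands with a p-value at or below the median of their file were kept, and rose to 10.8% when a mark in either experiment sufficed.

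The lists of genes fixed beforehand were compared with all other protein-coding genes for each mark. Of the 120 tests over 24 lists, 34 found a higher and 17 a lower share of marked genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over all tests). Genes are not independent replicates, and neighbouring members of any list can share an island. These p-values therefore compare genes within these libraries and do not count separate loci. Among genes with no other gene within 5 kb, few members of most lists were left, and 30 list results did not pass while 16 did. Those that passed were all 10 of the receptor genes, H3K27me3 and both marks at bipolar genes, H3K4me3 and both marks at Zfp genes, and H3K4me1 at neurogenic and ganglion cell genes. For lists other than the receptor lists, the background there includes 1175 receptor genes, of which 0 carried H3K4me3 or H3K4me1. They lower the shares of these marks among other genes.

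**Figure D2:**
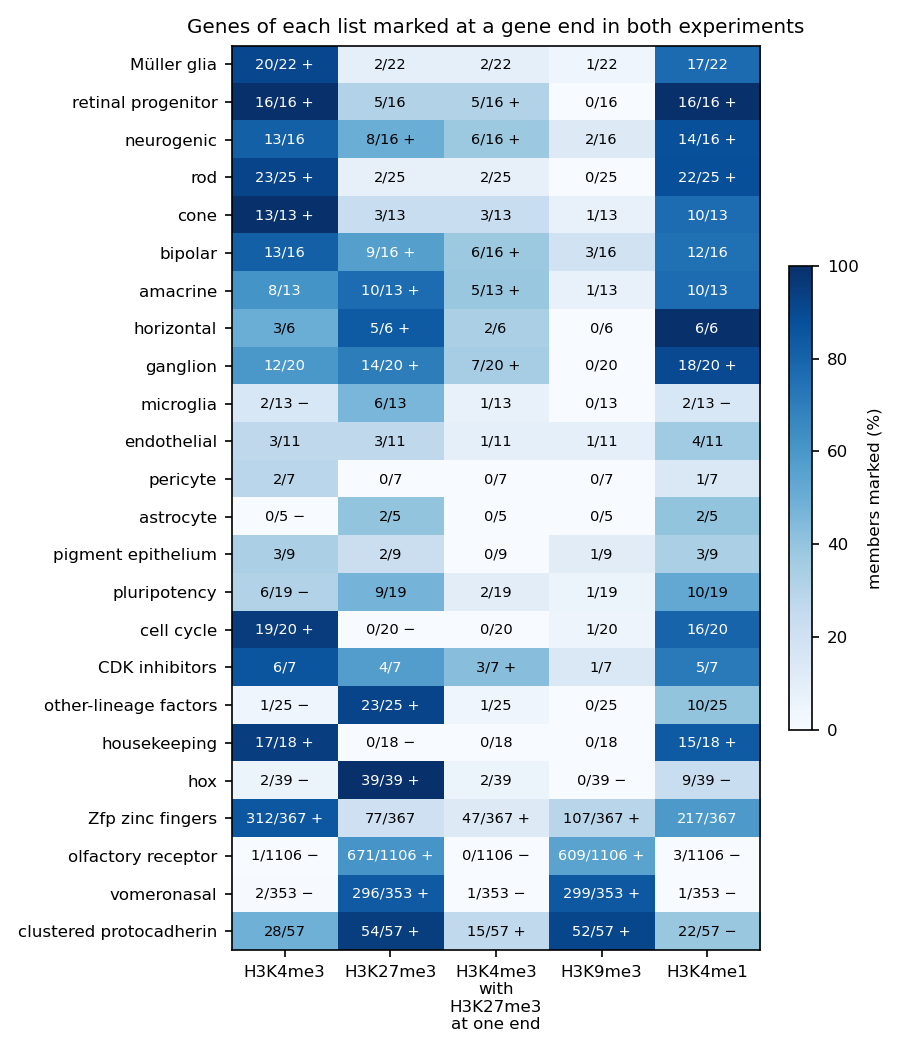
Members of each gene list marked at a gene end in both experiments, by mark. Each cell gives marked over all members and is shaded by the percent marked, and + or − stands for a share above or below other genes after adjustment; H3K27me3 was at 39 of 39 Hox genes and at 2 of 25 rod genes.

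Genes typical of Müller glia carried H3K4me3 more often than other genes. It was at 20 of 22 members, against 58.6% of other genes (log2 odds ratio 2.54, adjusted p = 0.00555, Fisher's exact test). Glul, which encodes glutamine synthetase (chromosome 1, 153899929 to 153909723), had an island of 13 kb in Exp1 and 10.4 kb in Exp2. At Slc1a3 (chromosome 15, 8634124 to 8710807) the islands were 6 and 4.8 kb wide. Apoe and Vim also had H3K4me3 without H3K27me3. H3K27me3 was at 2 members, which did not differ from other genes (adjusted p = 0.228, Fisher's exact test). They were Rlbp1, which encodes a retinaldehyde-binding protein, and the transcription factor gene Sox9, both with H3K4me3 at the same end. The water channel gene Aqp4 and Abca8a did not have H3K4me3 at an end in both experiments, though both had it within the gene, and Abca8a had it at an end in Exp1. The higher share of H3K4me3 did not pass among the islands with the lower p-values (log2 odds ratio 0.80, adjusted p = 0.39, Fisher's exact test).

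Retinal progenitor genes carried H3K4me3 and H3K4me1 at 16 of 16 members (adjusted p = 0.00161 and 0.000344, Fisher's exact test). Rax, Six3 and Six6, eye-field and progenitor transcription factor genes, had H3K4me3 without H3K27me3. Both marks lay at the same end of 5 members, including Pax6, Lhx2, Sox2 and Fgf15 (adjusted p = 0.00528, Fisher's exact test). Of 16 neurogenic genes, which drive the formation of neurons, 13 had H3K4me3, a share that passed only among genes with no other gene within 5 kb (7 of 8 against 35.6%, adjusted p = 0.0270, Fisher's exact test). The 35.6% includes 1175 isolated receptor genes, of which 0 carried H3K4me3, so this pass may rest on them. H3K27me3 was at 8 of the 16 neurogenic genes (adjusted p = 0.0430) and both marks at the same end at 6 (adjusted p = 0.000763, Fisher's exact test). Neurod1, Neurod4 and Dll1 had H3K4me3 without H3K27me3. Both marks lay at Neurog2, Neurod2 and, together with H3K9me3, at Atoh7. H3K27me3 without H3K4me3 lay at Neurog1 and, together with H3K9me3, at Olig2. At Neurod1 (chromosome 2, 79452637 to 79456636) the H3K4me3 islands were 11.8 and 10.8 kb wide, and at Atoh7 (chromosome 10, 63099785 to 63101280) 1.4 and 1 kb. The H3K27me3 share of the neurogenic list, with a log2 odds ratio of 1.72, did not pass in Exp1 alone (1.27, adjusted p = 0.166), Exp2 alone (1.43, adjusted p = 0.106) or either experiment (1.02, adjusted p = 0.278, Fisher's exact test). It also did not pass among the islands with the lower p-values (0.63), with windows of 2.5 kb (1.67) or over whole genes (1.62, smallest adjusted p = 0.0760, Fisher's exact test). Both marks at the same end, with 3.35, did not pass among the islands with the lower p-values (0 of 16, adjusted p = 1) or with 50% of the window covered (2.45, adjusted p = 0.0759, Fisher's exact test). Among genes with no other gene within 5 kb, neither result passed. H3K27me3 was at 3 of 8 there (log2 odds ratio 0.13) and both marks at 2 of 8 (adjusted p = 0.199, Fisher's exact test).

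Photoreceptor genes carried H3K4me3 in the Glast+ preparation. The share of rods and cones among the cells is not known, so the mark need not lie in Müller glia. H3K4me3 was at 23 of 25 rod genes (log2 odds ratio 2.73, adjusted p = 0.00153) and 13 of 13 cone genes (adjusted p = 0.00409, Fisher's exact test). H3K4me1 was at 22 rod genes (adjusted p = 0.00190, Fisher's exact test). H3K27me3 was at 2 rod genes, Guca1a and Guca1b, and 3 cone genes, Gngt2, Cnga3 and Rxrg, and neither share differed from that of other genes. At the 3 cone genes H3K4me3 lay at the same end, and this share was higher than among other genes in Exp1 alone (5 of 13, adjusted p = 0.00661), Exp2 alone (4 of 13, adjusted p = 0.0495), either experiment (6 of 13, adjusted p = 0.00471), with 50% of the window covered (adjusted p = 0.0494) and among genes with no other gene within 5 kb (2 of 3, adjusted p = 0.0427, Fisher's exact test), but not in the main test (adjusted p = 0.0753, Fisher's exact test). The rod share of H3K27me3 was lower than that of other genes in Exp1 alone (2 of 25 against 29.4%, log2 odds ratio -1.97, adjusted p = 0.0350) and with a mark in either experiment (adjusted p = 0.0138, Fisher's exact test). The rod transcription factor genes Nrl (chromosome 14, 55518978 to 55524981) and Crx (chromosome 7, 15865947 to 15879955) had H3K4me3 islands of 11.8 and 11.4 kb and of 26.6 and 25.8 kb, and no H3K27me3 island at their ends. Sag and Nr2e3 had H3K4me3 within the gene and at neither end. Among the islands with the lower p-values, H3K4me3 stayed at 23 of 25 rod genes (log2 odds ratio 3.78, adjusted p = 7.56e-07), while the cone list fell to 2 of 13 and its sign turned (log2 odds ratio -1.66, adjusted p = 0.206, Fisher's exact test). The cone list also did not pass with 50% of the window covered (log2 odds ratio 2.03, adjusted p = 0.0598, Fisher's exact test). Among genes with no other gene within 5 kb, neither the rod list (2 of 3, log2 odds ratio 1.59, adjusted p = 0.730) nor the cone list (3 of 3, log2 odds ratio 3.66, adjusted p = 0.170) passed (Fisher's exact test).

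Genes of the inner retinal neurons carried H3K27me3 more often than other genes. It was at 14 of 20 ganglion cell genes (log2 odds ratio 2.88, adjusted p = 7.06e-05), 10 of 13 amacrine genes (adjusted p = 0.000344), 5 of 6 horizontal cell genes (adjusted p = 0.0102) and 9 of 16 bipolar genes (adjusted p = 0.0136, Fisher's exact test). H3K4me3 was at 12 of the ganglion cell, 8 of the amacrine, 3 of the horizontal cell and 13 of the bipolar genes, and none of these shares passed. Under some alternatives 2 of them did. The ganglion cell share was lower among the islands with the lower p-values (1 of 20 against 40.7%, log2 odds ratio -3.16, adjusted p = 0.00340, Fisher's exact test). The bipolar share was higher in Exp1 alone (14 of 16, adjusted p = 0.0468) and over whole genes (16 of 16, adjusted p = 0.00355, Fisher's exact test). H3K27me3 without H3K4me3 lay at the ganglion cell genes Pou4f2, Pou4f3, Isl2 and Slc17a6, at the amacrine gene Tfap2a, and at the horizontal cell genes Onecut3, Lhx1 and Calb1. Of these, Isl2 and Tfap2a had H3K4me3 within the gene, and Onecut3 and Calb1 had it at an end in Exp2 alone. At Pou4f2 (chromosome 8, 78433009 to 78436647) the H3K27me3 islands were 45 and 30 kb wide, with no H3K4me3. Both H3K4me3 and H3K27me3 lay at Pou4f1, Gad1, Tfap2b, Onecut1, Onecut2, Vsx1, Grm6 and Isl1, of which Grm6 and Isl1 had H3K9me3 as well. H3K4me3 without H3K27me3 lay at Otx2, Trpm1, Prkca, Gad2 and Prox1, of which Gad2 had H3K27me3 in Exp2 and Prox1 in Exp1. Both marks at the same end were more frequent than among other genes for the ganglion (7 of 20), amacrine (5 of 13) and bipolar (6 of 16) lists (largest adjusted p = 0.00202, Fisher's exact test). The horizontal cell list passed for both marks in Exp1 alone (3 of 6, adjusted p = 0.0204), Exp2 alone (4 of 6, adjusted p = 0.00279) and either experiment (5 of 6, adjusted p = 0.000408), but not in the main test (2 of 6, adjusted p = 0.0860, Fisher's exact test). With only the islands of lower p-values, both marks lay at 0 genes of the ganglion, amacrine and bipolar lists (adjusted p = 1 for each, Fisher's exact test). The H3K27me3 share of the bipolar list, with a log2 odds ratio of 2.06, did not pass there (1.42, adjusted p = 0.220) or in Exp1 alone (1.61, adjusted p = 0.0537, Fisher's exact test). Among genes with no other gene within 5 kb, the H3K27me3 shares of the ganglion cell, amacrine and horizontal cell lists did not pass, with 4 of 5, 2 of 3 and 1 of 1 members (adjusted p = 0.223, 0.944 and 0.790, Fisher's exact test).

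The lists of retinal cell types were also set against each other, in 72 tests adjusted together. H3K27me3 was rarer at Müller glia genes than at ganglion and amacrine genes (adjusted p = 0.00146 for each), horizontal cell genes (adjusted p = 0.0122) and bipolar genes (adjusted p = 0.0264, Fisher's exact test). It was likewise rarer at rod genes than at ganglion and amacrine genes (adjusted p = 0.00117 for each), horizontal cell genes (adjusted p = 0.00999), bipolar genes (adjusted p = 0.0122) and neurogenic genes (adjusted p = 0.0477, Fisher's exact test). The only H3K4me3 difference that passed was between progenitor genes and ganglion cell genes (16 of 16 against 12 of 20, adjusted p = 0.0367, Fisher's exact test). That H3K4me3 difference, with a log2 odds ratio of 4.49, did not pass with Exp2 alone or either experiment (3.55 for both, adjusted p = 0.2 and 0.173), with windows of 2.5 kb (4.20, adjusted p = 0.0641) or over whole genes (3.89, adjusted p = 0.0752, Fisher's exact test). The H3K27me3 difference between rod and neurogenic genes had the same counts and log2 odds ratio (3.23) in each experiment alone, in either experiment and with windows of 2.5 kb, where only the adjustment over all pairs raised its p to 0.0530, and it fell to 1.76 among the islands with the lower p-values (adjusted p = 0.286, Fisher's exact test). Among those islands the differences of Müller glia and rod genes from bipolar genes, with log2 odds ratios of -3.38 and -3.57, did not pass (-3.15 and -2.54, adjusted p = 0.0817 and 0.101), nor did the former in Exp1 alone (-2.82, adjusted p = 0.0645, Fisher's exact test).

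**Figure D3:**
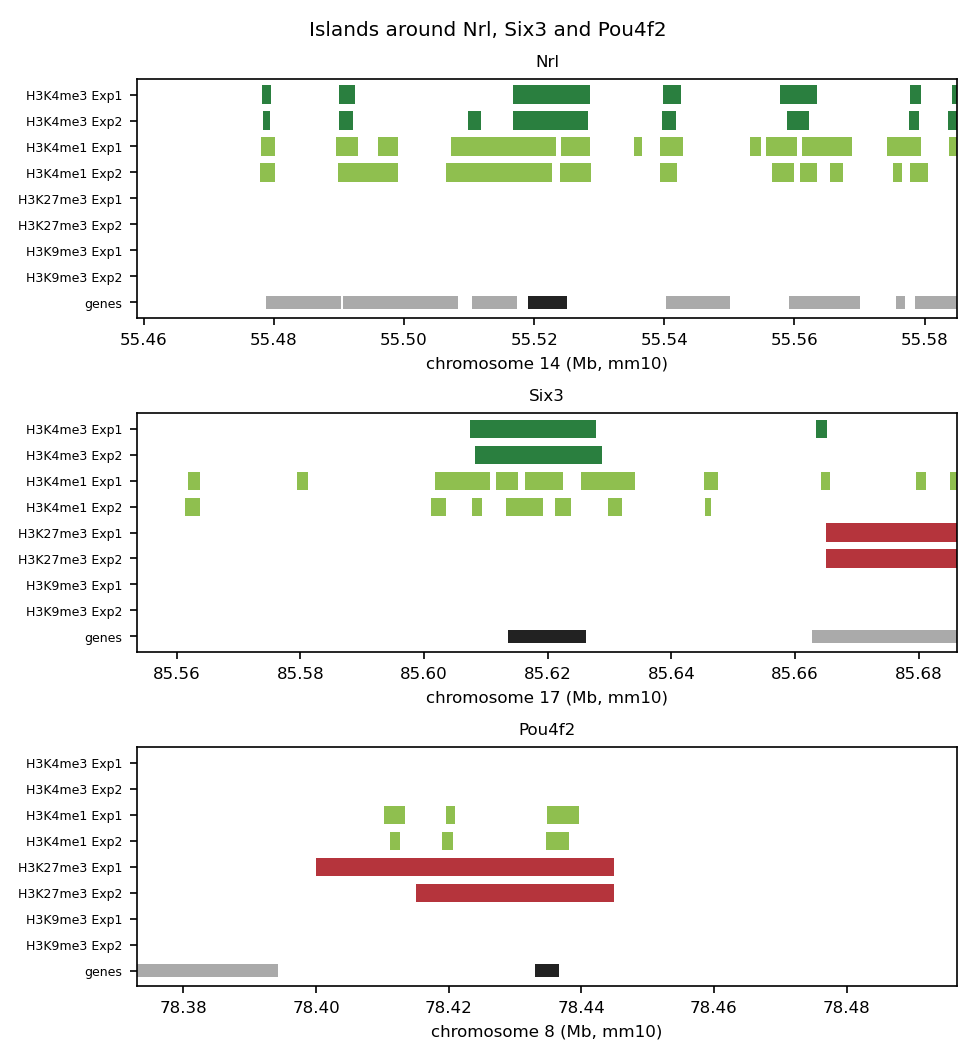
Islands of the 4 marks in both experiments around Nrl, Six3 and Pou4f2, by position in Mb on mm10; black bars are the named genes and grey bars their neighbours. Nrl and Six3 lay within H3K4me3 islands in both experiments, and Pou4f2 lay within H3K27me3 islands of 45 kb in Exp1 and 30 kb in Exp2.

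Of 5 lists of markers of other cells that a retinal preparation could hold, 2 carried H3K4me3 less often than other genes. It was at 2 of 13 microglia genes (log2 odds ratio -2.70, adjusted p = 0.00884) and 0 of 5 astrocyte genes (adjusted p = 0.0311, Fisher's exact test). The shares of 3 of 11 endothelial, 2 of 7 pericyte and 3 of 9 pigment epithelium genes were also below the 58.6% of other genes. In these small lists the difference did not pass (log2 odds ratios -1.78, -1.64 and -1.39, smallest adjusted p = 0.118, Fisher's exact test). Aif1, Cx3cr1, P2ry12 and Csf1r of microglia, Pecam1, Cdh5 and Cldn5 of endothelium, and Gfap and S100b of astrocytes had neither H3K4me3 nor H3K27me3 where both experiments were required. In Exp2 alone, Csf1r and Cldn5 had H3K4me3 and Cdh5 had H3K27me3. Rpe65, an enzyme gene of the pigment epithelium, lay in H3K27me3 islands of 390 and 315 kb. It also lay in H3K9me3 islands of 183 and 300 kb. The microglia share of H3K4me3 did not pass in Exp2 alone (log2 odds ratio -1.25, adjusted p = 0.262) or either experiment (-1.31, adjusted p = 0.167, Fisher's exact test). The astrocyte share, with a log2 odds ratio of -3.96, did not pass in Exp1 alone (-2.14, adjusted p = 0.251), either experiment (-2.26, adjusted p = 0.138), over whole genes (-2.36, adjusted p = 0.130), with 50% of the window covered (-3.63, adjusted p = 0.0563) or among the islands with the lower p-values (-2.92, adjusted p = 0.206, Fisher's exact test).

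Among genes of pluripotency, H3K4me3 was at 6 of 19 (log2 odds ratio -1.56, adjusted p = 0.0468, Fisher's exact test), including Klf4, Klf2 and Lin28a. Pou5f1, Dppa3, Prdm14 and, together with H3K9me3, Zfp42 carried H3K27me3 without H3K4me3, and Nanog carried no H3K4me3 and an H3K27me3 island, 135 kb wide, in Exp2 only. That lower share did not pass in Exp2 alone (-1.36, adjusted p = 0.118), either experiment (-1.42, adjusted p = 0.0702), windows of 500 bp (-1.48, adjusted p = 0.0750), with 50% of the window covered (-1.57, adjusted p = 0.0548), over whole genes (-1.52, adjusted p = 0.0672) or among genes with no other gene within 5 kb (-1.66, adjusted p = 0.541, Fisher's exact test). H3K27me3 was at 9 of the 19, which did not pass (adjusted p = 0.0563), but passed in Exp1 alone (11 of 19, adjusted p = 0.0253), Exp2 alone (10 of 19, adjusted p = 0.0467), either experiment (12 of 19, adjusted p = 0.0291) and without receptor genes in the background (adjusted p = 0.0244, Fisher's exact test). Cell cycle genes had H3K4me3 at 19 of 20 members (adjusted p = 0.00169) and H3K27me3 at 0 of 20 (adjusted p = 0.0198, Fisher's exact test). Ccna2, Ccnb1, Ccne1 and Cdk1 were among those with H3K4me3, and Ccnb2 had neither mark. Among islands with the lower p-values, the H3K4me3 share of cell cycle genes did not differ from other genes (log2 odds ratio -0.30, adjusted p = 0.90), nor did it with 50% of the window covered (1.32, adjusted p = 0.143, Fisher's exact test). Their H3K27me3 share, with a log2 odds ratio of -3.64, did not pass among those islands (-3.25, adjusted p = 0.0695) or without receptor genes in the background (-3.38, adjusted p = 0.0665, Fisher's exact test). Of 7 genes for inhibitors of cyclin-dependent kinases, Cdkn1c, Cdkn2a and Cdkn2b carried H3K4me3 and H3K27me3 at the same end (adjusted p = 0.0158, and 1 among the islands with the lower p-values, Fisher's exact test). Cdkn1b, Cdkn2c and Cdkn2d carried H3K4me3 without H3K27me3, and Cdkn1a H3K27me3 and H3K9me3, with H3K4me3 within the gene and at an end in Exp1 alone. Housekeeping genes such as Actb, Gapdh, Tbp and Ppia had H3K4me3 at 17 of 18 members (adjusted p = 0.00426) and H3K27me3 at 0 of 18 (log2 odds ratio -3.49, adjusted p = 0.0301, Fisher's exact test). The latter did not pass among the islands with the lower p-values (-3.10, adjusted p = 0.0991), with 50% of the window covered (-3.46, adjusted p = 0.0512) or without receptor genes in the background (-3.23, adjusted p = 0.0905, Fisher's exact test).

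Transcription factor genes of other lineages were covered by H3K27me3. It was at 23 of 25 such genes, including Gata2, Gata3, Gata4 and Gata5 (adjusted p = 3.95e-12), and H3K4me3 at 1, Tal1 (adjusted p = 6.77e-08, Fisher's exact test). Gata3 had H3K4me3 within the gene, and Gata2 had it at an end in Exp2 alone. All 39 Hox genes carried H3K27me3 (adjusted p = 1.77e-24), and 2 of them, Hoxa4 and Hoxa9, H3K4me3 as well (adjusted p = 1.30e-11, Fisher's exact test). Among genes with no other gene within 5 kb, H3K27me3 was at 2 of 3 other-lineage and 4 of 4 Hox genes, which did not pass (adjusted p = 0.944 and 0.0799, Fisher's exact test). In each experiment 1 H3K27me3 island covered each Hox cluster, and in Exp1 so did 1 H3K9me3 island. The p-values of Hox genes thus count genes that share islands, and not separate loci. The H3K27me3 islands over the Hoxa cluster were 395 kb wide in Exp1 and 365 kb in Exp2. The lower H3K9me3 share of Hox genes rested on 1 library, and did not pass among the islands with the lower p-values (adjusted p = 0.0610) or without receptor genes in the background (adjusted p = 0.0839, Fisher's exact test). H3K9me3 was at 0 of 39 Hox genes when both experiments were required (adjusted p = 0.0204), but at 39 of 39 in Exp1 (log2 odds ratio 8.63, adjusted p = 4.91e-30, Fisher's exact test) and 0 of 39 in Exp2.

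**Figure D4:**
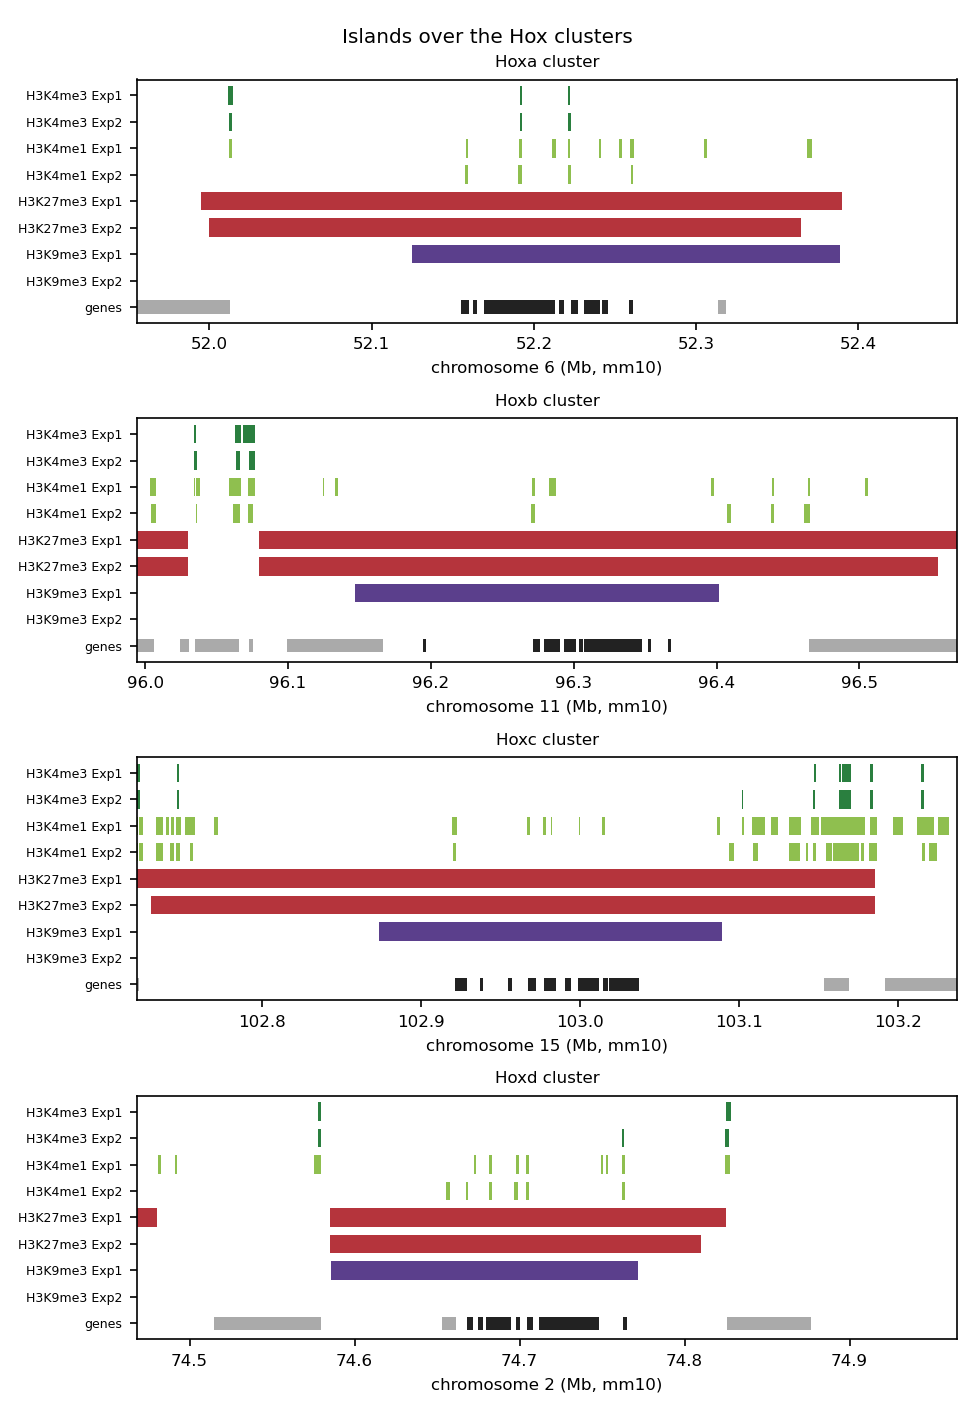
Islands of the 4 marks in both experiments over the Hox clusters and 200 kb on either side, by position in Mb on mm10; black bars are Hox genes and grey bars their neighbours. H3K27me3 islands covered all 4 clusters in both experiments, and H3K9me3 islands of 186 to 264 kb covered them in Exp1 only.

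Receptor and protocadherin gene families carried H3K27me3 and H3K9me3 more often than other genes. Neighbouring genes can share an island, and 1 H3K27me3 region on chromosome 7 held 48 receptor genes. The p-values of these families therefore count genes and not separate loci. Of 1106 olfactory receptor genes, 671 had H3K27me3 (log2 odds ratio 2.51, adjusted p = 1.12e-163) and 609 had H3K9me3 (log2 odds ratio 3.28, adjusted p = 4.36e-253), with both at 496 and H3K4me3 at 1 (Fisher's exact test). Of 353 vomeronasal receptor genes, 296 had H3K27me3 and 299 had H3K9me3 (log2 odds ratios 4.17 and 5.30), with both at 274. Of 57 clustered protocadherin genes, which encode neuronal adhesion molecules, 54 had H3K27me3 and 52 had H3K9me3 (log2 odds ratios 5.69 and 5.97), and 28 had H3K4me3, against 1 among the islands with the lower p-values. The Zfp zinc finger genes had H3K4me3 at 312 of 367 members (adjusted p = 4.00e-27) and H3K9me3 at 107 (log2 odds ratio 1.45, adjusted p = 1.44e-14, Fisher's exact test). H3K27me3 was at 77 Zfp genes, which did not differ from other genes (log2 odds ratio -0.19, adjusted p = 0.456, Fisher's exact test). Both repressive marks lay at 63 Zfp genes. Their H3K9me3 share did not pass among genes with no other gene within 5 kb (44 of 114 against 27.9%, log2 odds ratio 0.71, adjusted p = 0.0748, Fisher's exact test). The other genes there include receptor genes, with H3K9me3 at 513 of 882 olfactory and 255 of 293 vomeronasal receptor genes. These raise the share among other genes, so this result does not show that the Zfp share depends on neighbouring genes.

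Broad H3K4me3 islands were most frequent at rod and progenitor genes. The share of rods among the cells is not known, so those at rod genes need not lie in Müller glia. The widest 5% of islands at gene ends, 6.4 kb or more in both experiments, marked 651 genes, and the median over all genes with H3K4me3 was 2.8 kb. They were at 19 of 23 rod genes with H3K4me3 (log2 odds ratio 6.38, adjusted p = 3.47e-20) and 11 of 16 progenitor genes (log2 odds ratio 5.31, adjusted p = 2.21e-10, Fisher's exact test). Müller glia genes had 7 of 20 (log2 odds ratio 3.39, adjusted p = 0.000292), amacrine genes 3 of 8 (adjusted p = 0.0361) and housekeeping genes 4 of 17 (adjusted p = 0.0443, Fisher's exact test). Prph2, which encodes a protein of photoreceptor discs, had islands of 29.2 and 28 kb, Pax6 of 24.8 and 27.8 kb and Six3 of 20.4 and 20.6 kb. Among Müller glia genes the widest were at Gpr37 (16.2 and 11.8 kb) and Glul. Cone genes had 1 of 13, ganglion cell genes 0 of 12 and cell cycle genes 0 of 19, which did not differ from other genes. The housekeeping result, with a log2 odds ratio of 2.65, did not pass in Exp2 alone (2.18, adjusted p = 0.178, Fisher's exact test). The widest H3K4me3 islands at any gene lay over predicted genes on chromosome 8, where Gm21119 had 130 and 144.8 kb, and at Gas8 with 87.2 kb in both experiments. Gm21119 and Gas8 also carried H3K27me3 and H3K9me3. Reads were not used here, so whether they map uniquely at these genes is not known.

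**Figure D5:**
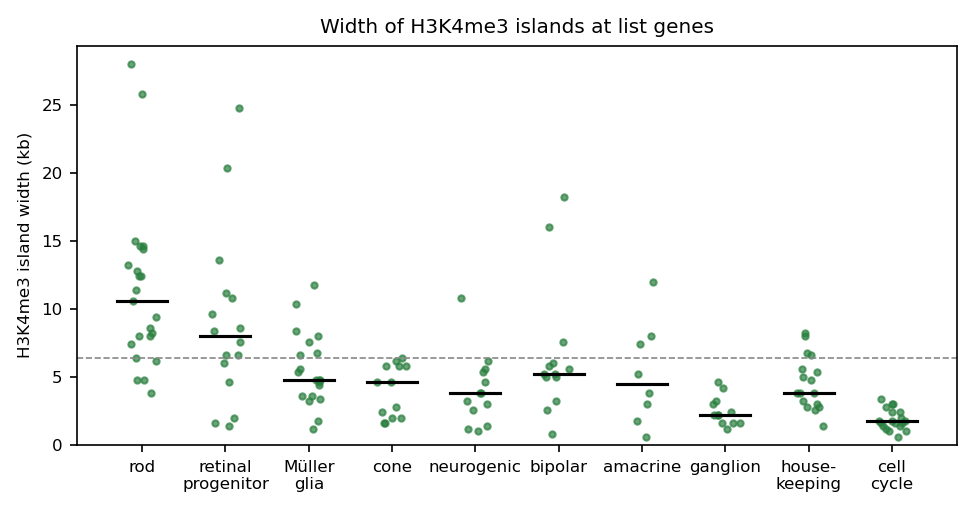
Width in kb of the widest H3K4me3 island at either end of each list gene, the smaller of the 2 experiments. Points are genes with H3K4me3, black lines are list medians, and the dashed line is the 6.4 kb limit; the median was 10.6 kb for rod, 8 kb for progenitor, 4.8 kb for Müller glia and 1.8 kb for cell cycle genes.

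Several of the widest H3K27me3 and H3K9me3 regions overlapped on chromosomes 12, 14, 7 and X (mm10). The H3K27me3 region at the start of chromosome 14 (3000001 to 7735000) spanned 4735 kb and held 76 protein-coding genes, among them Gm2888 and Gm2897. H3K9me3 covered 3351 kb of chromosome 12 (17766001 to 21117000), which held 21 genes, including Zfp996, and H3K27me3 covered 3295 kb there (17820001 to 21115000). Whether reads map uniquely in these regions is not known, and the regions were kept in the overlap between marks.

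H3K4me1 regions away from gene ends and without H3K4me3 were counted within and near each gene as putative distal sites. Of 33380 regions shared by both experiments, 14531 lay over 2.5 kb from any gene end, and 5365 genes had 1 or more within 10 kb of their span. The median was 0 for 23 of the 24 lists and for most random lists, so the planned comparison of medians could not find fewer sites and is not read as a result. By their mean count against 10000 random lists matched on gene length, a measure added after the data were seen, olfactory and vomeronasal receptor genes had fewer (0.00362 and 0.0113 per gene, adjusted permutation p = 0.0024 for each). The means of 0.636 for Müller glia genes and 1.38 for progenitor genes did not differ from random lists (adjusted permutation p = 0.556 and 0.36).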

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

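Of 66 list results, 37 kept their direction and side of the threshold under all settings that covered them other than isolated genes. They include H3K4me3 at rod and progenitor genes, H3K27me3 at ganglion, amacrine, horizontal, other-lineage and Hox genes, and both repressive marks at receptor genes and protocadherins. Windows over whole genes, isolated genes, overlap without receptor genes and the list mean of distal regions were chosen after seeing the data. Causes of the changes between settings were not tested except where the construction shows them. Depth is unknown, so weak islands cannot be told from missed ones.

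Keeping islands with a p-value at or below the median of their file cut their mean number by construction, from 18465 to 9233 for H3K4me3, 44771 to 22389 for H3K4me1, 5924 to 2962.5 for H3K27me3 and 7655.5 to 3828 for H3K9me3. With these islands, genes with H3K4me3 and H3K27me3 at the same end fell from 5.74% to 0.95%, genes with neither rose from 24.8% to 41.8%, and genes with H3K4me1 fell from 54.6% to 32.3%. H3K4me3 length at gene ends was 46.2% and H3K9me3 length 2.58%. Signs turned for H3K4me3 at cone genes (log2 odds ratio -1.66) and cell cycle genes (-0.30), and at protocadherins for H3K4me3 with H3K27me3 (-0.15) and for H3K4me1 (0.30). Windows of 2.5 kb raised the length at gene ends, by construction, to 58.2% for H3K4me3, 25.1% for H3K4me1, 7.59% for H3K27me3 and 4.79% for H3K9me3.

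With 1 experiment left out, log2 overlap ranged from 2.93 to 3.40 for H3K4me3 with H3K4me1, -0.42 to 0.18 for H3K4me3 with H3K27me3, -0.77 to -0.0592 for H3K4me3 with H3K9me3, -1.55 to -0.31 for H3K4me1 with H3K27me3, -3.19 to -1.11 for H3K4me1 with H3K9me3 and 1.43 to 1.56 for H3K27me3 with H3K9me3. With Exp1 alone or a mark in either experiment, H3K9me3 at Hox genes turned from depleted to enriched (log2 odds ratios 8.63 and 8.49, against -3.78 with Exp2 alone). The experiments share a number across marks and nothing in the labels says that it marks shared animals. As a replicate block, that H3K9me3 result was 2.49, and log2 overlap was 3.16, -0.12, -0.41, -0.93, -2.15 and 1.5 in the order of the pairs above, where H3K4me3 with H3K9me3 no longer passed because Exp2 alone did not. The replicate block gave 8.16% of genes with both marks at the same end.

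A mark in either experiment raised genes with both marks at the same end to 10.8%, and windows over whole genes to 8.63%. Without receptor genes in the background, list results with a lower share were 8 instead of 17. Of the 17, 6 belong to the receptor lists, which this setting leaves out, and 3 no longer passed: H3K27me3 at cell cycle and housekeeping genes and H3K9me3 at Hox genes (adjusted p = 0.0665, 0.0905 and 0.0839, Fisher's exact test). Of the results with a higher share, H3K4me1 at neurogenic and housekeeping genes no longer passed (adjusted p = 0.0649 and 0.0890, Fisher's exact test). Among isolated genes, 14 were higher, 4 of them of receptor lists, and 6 lower, all of receptor lists. Lists other than the neurogenic and receptor lists kept under 50% of their members there, and 30 results no longer passed. They include H3K4me3 at rod, cone, progenitor and Müller glia genes, H3K27me3 at ganglion, amacrine, horizontal, other-lineage and Hox genes, and H3K9me3 at Zfp genes. In this setting, genes with H3K4me3 without H3K27me3 were 30.3%, H3K27me3 without H3K4me3 31.5%, H3K9me3 28.1% and H3K4me1 31.0%. Some results beyond those in the report passed only under an alternative. Shares of H3K4me1 were higher at Müller glia, cone, bipolar, horizontal, cell cycle and Zfp genes. Those of H3K4me1 at other-lineage genes and of H3K9me3 at rod genes were lower. By the mean, 2 lists differed in distal H3K4me1, where the median could not find fewer. Transcription starts taken as the most 5' of each gene and a background of CpG-rich promoters were not run, since strand and sequence were not used here.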

Other observations

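Other gene families were grouped after the data were seen by the letters that open their symbols (111 families of 20 or more genes, 777 tests adjusted together). Differences between families or between marks were not tested. Genes of a family that lie side by side can share an island, so the p-values count genes and not separate loci. H3K27me3 and H3K9me3 together lay at 28 of 28 Defa genes, which encode intestinal alpha-defensins, 19 of 22 Mup major urinary protein genes, 35 of 40 Scgb secretoglobin genes and 41 of 46 Pramel genes (largest adjusted p = 1.86e-14, Fisher's exact test). The Klk kallikrein genes carried H3K27me3 at 26 of 26 and H3K9me3 at 1 of 26. Keratin genes carried H3K27me3 at 28 of 53 and H3K9me3 at 0 of 53. Over all protein-coding genes, H3K27me3 lay at 23.3% and H3K9me3 at 13.4%. None of the 4 marks lay at 21 of 21 Lce genes of the skin's cornified envelope, 42 of 56 Krtap hair keratin-associated genes, 29 of 42 Defb genes and 42 of 83 Il genes (largest adjusted p = 2.47e-09, Fisher's exact test). H3K4me3 was at 49 of 49 Mrpl genes for mitochondrial ribosomal proteins.

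Gene classes other than protein-coding genes were described without a test. Pseudogenes carried H3K27me3 at 33.0% and H3K9me3 at 30.8% of 9944 genes, and the V segments of antigen receptors at 76.4% and 65.5% of 394. H3K4me3 was at 19.7% of lncRNA genes and 51.7% of tRNA genes.

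All tests in the next 2 paragraphs were chosen after the data and the patterns were seen. For neighbouring genes, a small minority of rods and receptor gene clusters, the bounds were set before the test itself was run, and for the others after the values they use were known. The background without receptor genes, the widths of housekeeping genes and the counts by width among islands with the lower p-values were added later, and with them neither of the first 2 bounds decides. The test of the H3K9me3 antibody was also changed after its result was seen. It was first counted over genes marked in both experiments, where 0 of 62 Hox and other-lineage genes with H3K27me3 carried H3K9me3. When all 39 Hox genes proved to carry it in Exp1 alone, it was recounted for each experiment, with each Hox cluster as 1 locus because 1 island covers its genes. By genes, Exp1 gave 42 of 62 (67.7%), above the bound of 50% set for antibody binding, and by loci it gave a value between the bounds, so the outcome for Exp1 rests on that choice.

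Rod and cone genes carried H3K4me3 in cells sorted for Glast, a marker of glia. Islands of neighbouring genes were not excluded. Of isolated rod and cone genes, 5 of 6 (83.3%) carried H3K4me3, against 35.7% of other isolated genes (p = 0.0244, Fisher's exact test). That p-value rests on 1175 isolated receptor genes, of which 0 carried H3K4me3. Without them 43.6% of the others did and the difference did not pass (p = 0.0924, Fisher's exact test), so the bound set before the test was wrong in using all isolated genes. A small minority of rods among the cells was not excluded either. The median island width at rod genes was 2.21 times that at Müller glia genes (permutation p = 0.00015), which met the bound, but the bound was wrong because width does not follow the share of cells. Housekeeping genes, which are active in all cells, had a median of 3.8 kb, against 4.8 kb for Müller glia and 10.6 kb for rod genes. Among the islands with the lower p-values, 23 of 23 rod genes kept H3K4me3, against 12 of 20 Müller glia and 15 of 17 housekeeping genes. This does not decide either, since 89.4% of other genes with islands as wide as the narrowest at a rod gene kept it too, against 69.4% of other genes of any width. A large share of rods remains open, since H3K27me3 lay with H3K4me3 at 2 of 20 Müller glia genes (10%), which decides nothing. H3K4me3 at rod genes in the Müller glia themselves was not tested, as no rod gene was on another list and the design holds no sample of rods.

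H3K27me3 and H3K9me3, often found apart, shared much of their territory. Receptor gene clusters are not the whole cause, because log2 overlap was 1.85 without 100 kb around olfactory and vomeronasal receptor genes (permutation p = 0.002). For an H3K9me3 antibody that also binds H3K27me3, 0 of 27 loci with H3K27me3 (0%) carried an H3K9me3 island in Exp2. This shows no such binding strong enough to give islands there. Weaker binding is not excluded, since depth is unknown and the bound was set after this count was known. In Exp1 such binding stays open, where 7 of 27 loci (25.9%) carried H3K9me3. They were all 4 Hox clusters, with island p-values of 7.83e-23 or below, and 3 of 23 other-lineage genes. The higher count by genes comes from the 39 Hox genes in those clusters, which are not separate loci. An H3K27me3 antibody that also binds H3K9me3 could not be told apart from true overlap, as 68.4% of the H3K9me3 length lay in H3K27me3 islands, between the bounds of 50% and 80%. Several of the widest regions of both marks coincide, and whether reads map uniquely there is not known. These regions were kept in the overlap, and the control behind the islands is not given, so signal common to both marks was not tested.

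Genes marked by H3K9me3 in 1 experiment alone were counted for H3K27me3. Of 729 such genes in Exp1, 504 (69.1%) carried H3K27me3 there, and of 309 in Exp2, 137 (44.3%) did. Of all genes with H3K9me3, 3224 of 3664 in Exp1 and 2628 of 3244 in Exp2 carried H3K27me3. Both shares were thus below that of all H3K9me3 genes of the same experiment. These differences were not tested.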
